A study of Homo sapiens with 6 samples.

How the data were processed

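The series compared nucleosome positions upstream of microRNAs in the MCF7, MALME and UACC62 lines, with 2 arrays per line. Per the labels, genomic DNA cleaved by hydroxyl radicals was labelled with Cy3 and gel-extracted mononucleosomal DNA with Cy5. The labels number the samples of a line 1 and 2 and do not say whether they came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

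The spot intensity values of 4 arrays were deposited as scanned, from NimbleScan 2.3.78 per the file headers, with positions in build HG18. Any background step is not given in the sources used here. The 387011 tiled probes lie in 295 regions, and 2296 probes of random sequence were left out of all tests. The table of all 6 arrays holds a deposited ratio per probe, wavelet denoised per the labels. Its columns have a median of 1, are on a linear scale and run as Cy5 over Cy3, judged by correlations of 0.889 to 0.914 between their log2 and the unsmoothed scanner log2 ratio. For MCF7, whose scanner values were not used here, the same direction was judged from correlations of 0.569 to 0.781 with the other columns and of -0.742 and -0.687 with the mean log2 Cy3 of the 4 scanned arrays, where the other columns gave -0.886 to -0.788. Its scale was taken to be that of the other columns. Every per-sample column was matched to a sample.

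Scanner values were used as log2 of Cy5 over Cy3, centred on the array median, with no loess or quantile step, because most probes of such an array carry signal. The ratio table was used as log2 after a floor of 0.1, centred on the median; the floor was chosen after its unit was seen and before any test. Probe values were averaged in adjoining 200 bp windows with at least 10 probes, and over whole regions. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg, adjusted p under 0.05). UACC62 against MALME used the 4 scanner arrays. Comparisons with MCF7 used all 6 arrays of the ratio table, with a coefficient per line and a shared spread.

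A depleted segment was a run of at least 100 bp in which the log2 ratio, as a running median of 5 probes (none for the ratio table), lay under the array's 10th percentile. A line had a segment where both arrays did, over at least 50 bp. Segments were shared if they overlapped by at least 0.5 of the shorter, against 100 circular shifts within regions. Autocorrelation was taken at lags up to 500 bp. Segments, correlations and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

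The files give positions and no names. Regions were named from the table of RefSeq genes (GRCh38.p14), used for names and neighbouring genes only and never for positions. Regions of full length reached 20 kb upstream and 1 kb downstream of the microRNA. Such a region took a name when its hairpin or cluster length and its spacing matched a single microRNA or cluster. Spacing was taken to at least 1 other tiled region, within 20 bp. A cluster length that was unique also gave a name. The 91 shorter regions, among them those of MIR92A1 and MIR301A, had no length to match. Any name there came from 1 end of a microRNA and the spacing alone. Together these rules named 226 of 295 regions, 182 with a strand. Without names from a unique cluster length, a mean of 3.2 regions, and at most 12, were named after random shifts. Cluster length alone named 5 regions, against a mean of 0.75 after random changes of length. Names are therefore inferred, and the other regions are called unnamed. The lists hold 257 names of 238 different microRNAs, matched through the symbols and older names in that table, and 169 of the 238 lay in a named region.

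Windows were named by a rule fixed before the data were examined: in each direction the 10 largest differences among windows past the threshold whose arrays of both sides did not overlap, at most 1 per region, or, where fewer than 5 passed, the 5 smallest p, given as not passing. The microRNA lists and the microRNAs with a deepest window were fixed then too. They are the epithelial, melanocyte and melanoma, breast and luminal, let-7, mir-17, mir-34, HOX, neural, muscle, blood cell, pluripotency, chromosome 14 imprinted, chromosome 19 placental and broadly expressed lists.

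The fits were tested on simulated windows with the measured means and spreads, of which 200 of 20765 were changed. The simulated noise was independent and of equal spread for all arrays of a window. For UACC62 against MALME 0% of windows changed by 1 on the log2 scale were recovered, 38% of those changed by 2 and 84% of those changed by 4. For melanoma against MCF7 the shares were 52%, 86% and 98%. The size of 4 was added after the smaller sizes gave few calls between UACC62 and MALME. Planted depleted runs of 250 bp were found in 100% of 120 cases, and 69.4% of the segments found lay on a planted run. Segments of the arrays were shorter, with a median length of 120 bp in MALME and UACC62. The shares for planted runs therefore do not give the recovery or the precision of the segments reported below. Alternatives covered background correction, scaling, window width and summary, the prior, the source of values, pairing by replicate number, and each array left out.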

Results

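Nucleosomal DNA was measured across 295 tiled regions upstream of human microRNA genes in 3 cancer cell lines. MCF7 is a breast cancer line, and MALME and UACC62 are melanoma lines. Each line had 2 arrays, 6 in all, and 387011 probes were spaced mostly 10 bp apart. On every array mononucleosomal DNA, released by micrococcal nuclease and cut from a gel, carried Cy5, and genomic DNA of the same line carried Cy3. The value compared was the log2 ratio of Cy5 over Cy3, mononucleosomal over genomic signal, and higher or lower refers to that ratio, in which either channel can differ. For 4 arrays, those of MALME and UACC62, spot intensities were at hand. The 2 MCF7 arrays were read only from the deposited denoised ratios, whose direction was judged for MCF7 from correlations with the other columns and with Cy3. Their scan day is not given in the sources used here, so a batch shared by both cannot be separated from the line in any comparison with MCF7.

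Signal strength differed between arrays. The median Cy3 intensity was 848 on MALME replicate 1, 993 on MALME replicate 2, 919 on UACC62 replicate 1 and 702 on UACC62 replicate 2. The median Cy5 intensity was 1818, 2024, 1897 and 3994 on the same arrays. Probes of random sequence reached 81.3%, 68.9%, 64.1% and 87.0% of the median Cy5 intensity, and 49.9%, 41.9%, 43.3% and 39.5% of the median Cy3 intensity. The standard deviation of the log2 ratio was 0.82, 0.82, 0.83 and 1.37. Across probes of an array, which are not independent replicates, the log2 ratio fell as the Cy3 intensity rose, with r of -0.90, -0.84, -0.84 and -0.97. Cy3 is the denominator of the ratio, so part of this is built in. The number of arrays limits the precision of every value given here.

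The first comparison asked where the melanoma lines differed from the breast cancer line. Melanoma stands below for MALME and UACC62 only, and n = 4 counts their arrays, 2 per line. The p-values measure spread between arrays of a line, so variation between lines of a cancer type is not covered. Among 200 bp windows that passed and whose arrays did not overlap, one near MIR148A had the largest difference. It was 3.42 higher in melanoma on the log2 scale (SE 0.68). It lay on chromosome 7 from 25956264 to 25956463 (HG18, as all positions here). Its mean was -2.30 ± 1.15 (SD, n = 2) in MCF7 and 1.24 ± 1.00 (SD, n = 4) in melanoma. Single arrays stood far apart, at -1.49 and -3.11 in MCF7, 0.25 and 2.39 in MALME, and 1.75 and 0.59 in UACC62. A window of the mir-17 cluster region, in the region named for its member MIR92A1, was 1.89 higher (SE 0.23), at -1.23 ± 0.05 (SD, n = 2) in MCF7 against 0.78 ± 0.38 (SD, n = 4). A window upstream of MIR9-2, a microRNA of neural tissue, was 1.84 higher (SE 0.12). Windows of MIR125B2, MIR568 inside ZBTB20, MIR663A, MIR181C/MIR181D, MIR190A inside TLN2 and MIR301A inside SKA2 were higher by 1.74 to 2.77, as was an unnamed region of chromosome 20 by 2.23.

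Windows with a lower ratio in melanoma included one of MIR153-2, inside PTPRN2, where the difference was -2.30 (SE 0.19). Its mean was 1.27 ± 0.28 (SD, n = 2) in MCF7 and -0.90 ± 0.21 (SD, n = 4) in melanoma. A window of MIR124-1, a neuronal microRNA, differed by -1.64 (SE 0.15) on chromosome 8 from 9808308 to 9808507. A window of MIR196A2, in a HOX gene cluster, differed by -1.73 (SE 0.15), with -0.03 ± 0.12 (SD, n = 2) in MCF7 and -1.63 ± 0.18 (SD, n = 4) in melanoma. The window of MIR29C/MIR29B2 differed by -1.61. Windows of MIR658/MIR659, MIR593 inside SND1, MIR549A, MIR637 inside DAPK3 and MIR602 differed by -2.11 to -1.68, and one of an unnamed region of chromosome 22 by -1.60.

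In all, 1981 of 20765 windows passed (limma, two-sided, Benjamini-Hochberg adjusted p under 0.05), 1272 higher and 709 lower in melanoma, in 282 regions. The differences above are given after subtracting the median over all windows, 0.13, while the adjusted p tests the unsubtracted difference. Tested against that median, 1832 windows passed, 561 above and 1271 below it, so the split of directions followed the centring. Quantile normalization called 3446 higher and 3682 lower, and dividing each array by its median absolute deviation called 5668 higher and 1827 lower. The named windows had adjusted p from 0.00767 to 0.0458, and all 20 kept their direction in every setting run on 200 bp windows. Read as linear ratios in place of log2, 1 window passed. All 1981 kept their direction in the same settings. Kept directions are little support, since these windows were picked for a clear separation of the same arrays. In 1979 of the 1981 windows all 4 melanoma arrays lay on one side of both MCF7 arrays, an order found in 50.6% of all windows and in 13.3% by chance. Without either MCF7 array or either MALME array, 0 windows passed, while 10126 passed without UACC62 replicate 1 and 7767 without UACC62 replicate 2. The window differences also correlated with Cy3 brightness across windows (r = -0.49). That brightness came from the melanoma arrays, whose Cy3 is the denominator of the melanoma ratios.

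**Figure D1:**
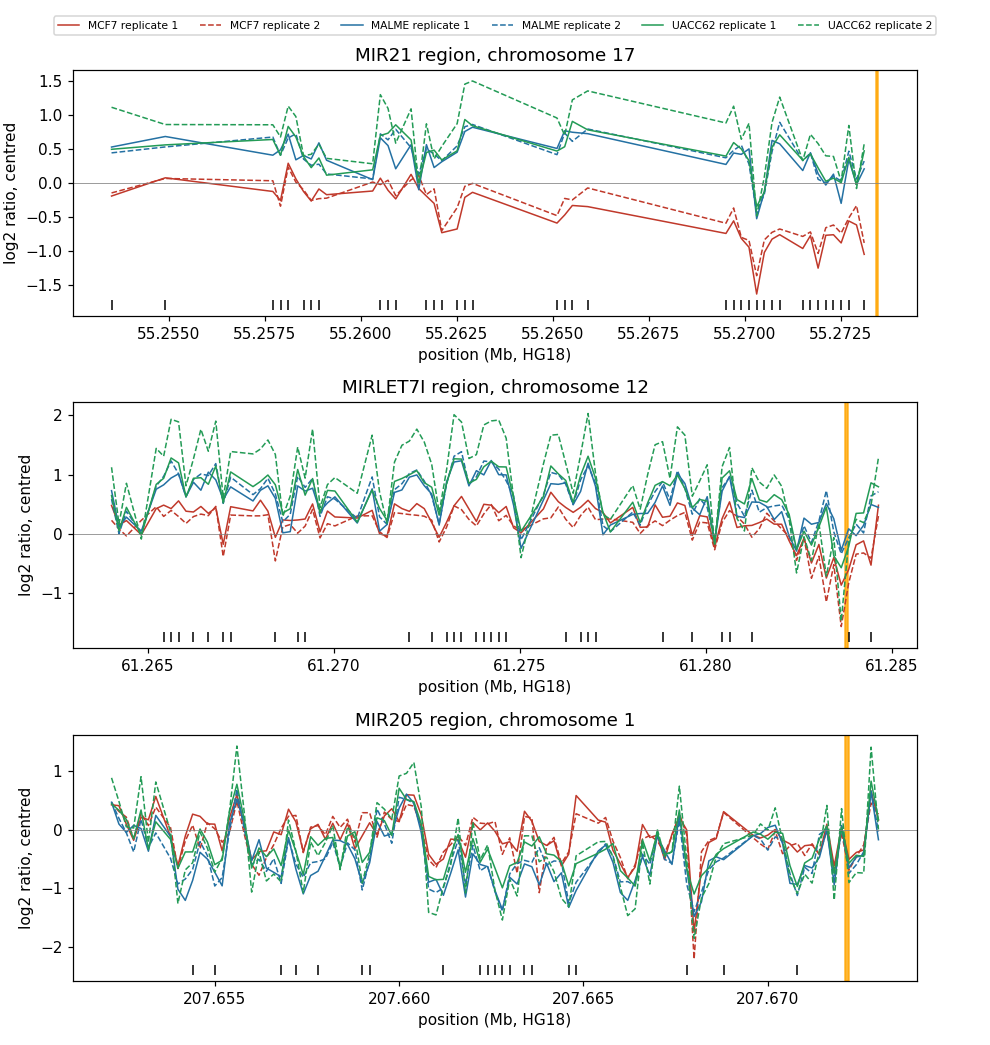
Centred log2 ratio of 200 bp windows against position (Mb, HG18) for the regions of MIR21, MIRLET7I and MIR205, one line per array (solid for replicate 1, dashed for replicate 2) and a colour per cell line. Black ticks mark windows called between the melanoma lines and MCF7 (37, 31 and 20 windows), and the orange band is the microRNA.

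Whole regions were compared by their mean. MIR21, a microRNA raised in many tumours, lies within VMP1, and its region on chromosome 17 (55253409 to 55274480) was 0.80 higher in melanoma (SE 0.09, adjusted p = 0.0148), relative to a median region difference of 0.11. Without that subtraction, the test used for the 19 regions called below, its difference was 0.91 (adjusted p = 0.00524). The other region differences are given after the subtraction too. The mean of the MIR21 region was -0.43 ± 0.07 in MCF7, 0.40 ± 0.02 in MALME and 0.57 ± 0.20 in UACC62 (SD, n = 2 arrays each, adjusted p from limma). Of the 43 windows of MIR21, 37 were called, all higher in melanoma. The region of MIR92A1 was 0.59 higher (SE 0.08). That of MIR301A, on chromosome 17 (54582279 to 54588307), was 0.47 higher (SE 0.08). Also on chromosome 17, an unnamed region (58355308 to 58376405) was 0.30 higher, with 22 of 67 windows called and all higher. MIR301A, MIR21 and this unnamed region follow each other in the tiling of that chromosome, so their shifts may not be independent. MIR548A3 was 0.53 higher (SE 0.11), MIR550B1 inside ZNRF2 0.44 higher (SE 0.10) and MIR449A inside CDC20B 0.28 higher (SE 0.07). MIRLET7I, of the let-7 family, was 0.42 higher with 31 of 93 windows called, and MIR181B1/MIR181A1 was 0.47 higher with 27 of 84 windows called. MIR205, a microRNA of epithelial cells, went the other way, with 20 of 99 windows called and all 20 lower in melanoma.

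The test called 19 of 295 regions, 19 higher and 0 lower. Against the median region difference 4 passed, with MIR21, MIR92A1 and MIR301A above it and MIR205 below it (-0.40, SE 0.07, adjusted p = 0.0425). Leaving out either MCF7 array gave 0 regions (limma adjusted p of MIR21 0.154 without replicate 1 and 0.184 without replicate 2), leaving out MALME replicate 1 or 2 gave 12 or 7, and leaving out UACC62 replicate 1 or 2 gave 167 or 164. Quantile normalization called 88 higher and 79 lower, and 0 regions passed when the values were read as linear ratios.

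**Figure D2:**
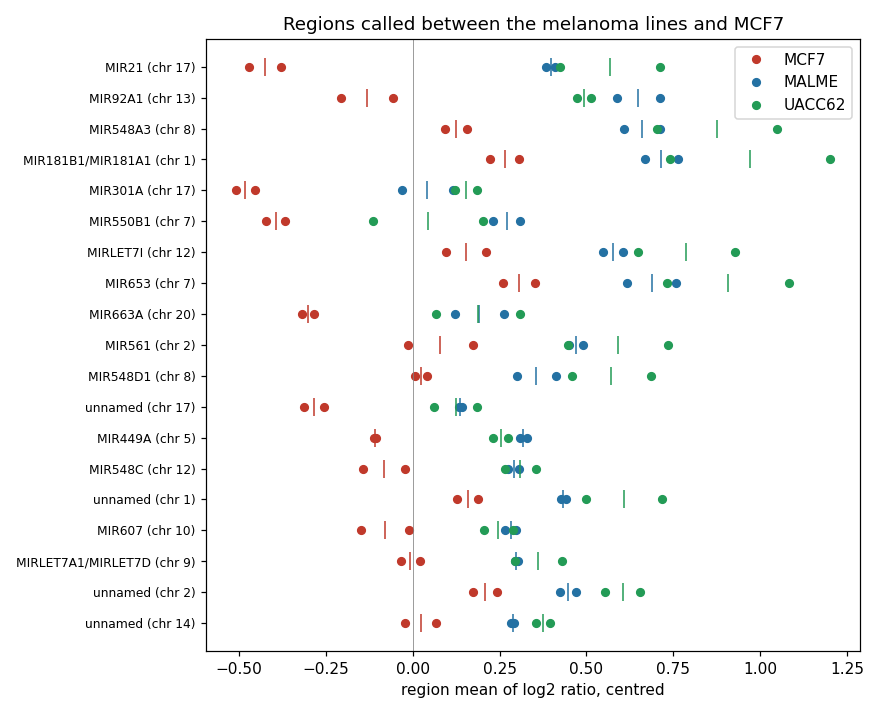
Mean centred log2 ratio (x axis) of the 19 regions called between the melanoma lines and MCF7 (y axis). Points are single arrays, upright bars are line means of 2 arrays, and MIR21 has the widest separation, at -0.43 in MCF7 and 0.57 in UACC62.

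The deepest 200 bp window was located in 25 regions of microRNAs chosen beforehand. In MIR21 it lay at the same place in all 3 lines, 3100 bp upstream (chromosome 17, 55270209 to 55270408), at -1.49 ± 0.19 in MCF7, -0.48 ± 0.06 in MALME and -0.41 ± 0.10 in UACC62 (SD, n = 2). In MIR205 it lay 4100 bp upstream in every line, at -1.98 ± 0.33, -1.44 ± 0.06 and -1.48 ± 0.53. MIR211, a melanocyte microRNA within TRPM1, had it 12791 bp upstream, at -2.31 ± 0.01, -1.83 ± 0.28 and -2.08 ± 0.79. In MIRLET7I it lay 100 bp upstream, and in MIR124-1 1216 bp upstream. The place was shared within 200 bp by the 3 lines in 10 of the 25 regions, against a mean of 0.046 for random windows, and by MALME and UACC62 in 19. These windows were also bright in the mean Cy3 of the 4 scanned arrays, at a median percentile within their region of 97.4 in MCF7, 99.0 in MALME and 100 in UACC62. Random windows were drawn without regard to brightness. Brightness alone could therefore give places shared above random windows, and a shared place is no evidence of a shared depletion.

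Called windows of the remaining microRNAs chosen beforehand went both ways. All called windows were higher in melanoma in the regions of mir-203 (12), mir-193b (11), mir-31 (11), the mir-17 cluster (7), mir-200b (3), mir-155 (3), mir-16-1 (1) and mir-23a (1). In mir-211 both called windows (2) were lower. The called windows split between directions in let-7a-1 (14 higher, 2 lower), mir-137 (9 and 4), mir-10b (9 and 3), mir-204 (3 and 6), mir-182 (5 and 6), mir-375 (4 and 2), mir-10a (3 and 3), mir-29a (1 and 5), mir-125b-1 (1 and 2), mir-124-1 (7 and 7), and in mir-146a, let-7a-3 and mir-196a-2 (1 and 1 each).

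Grouped by the lists fixed beforehand, the breast and luminal list had 87 of 516 windows called, 79 higher and 8 lower in melanoma, of which 37 came from MIR21. Its count adjusted over the list alone was 126. Against the median difference, 53 of its 73 called windows were higher. The pluripotency list had 14 of 93 windows called, 11 of them higher, and 28 adjusted over the list alone. The mir-17 clusters had 14 of 125 windows called, with 11 higher and 3 lower, and 18 adjusted over the list alone. Higher windows stayed the larger part of these lists with quantile normalization, with division by the median absolute deviation and against the median difference. In that order, 16 of 30, 29 of 38 and 6 of 10 called windows of the pluripotency list were higher. For the mir-17 clusters they were 24 of 40, 40 of 48 and 7 of 12. Several of these counts lay near an even split. The pluripotency and mir-17 lists held 2 regions each, and MIR21 gave many of the breast and luminal windows, so single regions can carry these directions.

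In other lists higher windows were the larger part with both scalings but not against the median difference. The let-7 list had 75 called, of which 63 were higher and 12 lower, and 109 adjusted over the list alone. The HOX list had 36, with 26 higher and 10 lower, and 40 adjusted over the list alone. Blood cell microRNAs had 83, with 64 higher and 19 lower, and 132 adjusted over the list alone. For the placental cluster of chromosome 19, tiled as 1 region, there were 6, with 4 higher and 2 lower, and 4 adjusted over the list alone. Against the median, 20 of 50, 19 of 41, 25 of 55 and 2 of 8 called windows of these lists were higher. Of 47 microRNAs listed for the imprinted cluster of chromosome 14, only MIR370 lay in a named region. That region had 9 windows called, with 6 higher and 3 lower, and 10 adjusted over the list alone, while quantile normalization called 18 of 36 higher and the test against the median 1 of 8.

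In the remaining lists the larger direction changed with the scaling or no direction led. The melanocyte and melanoma list had 42 of 569 windows called, 21 in each direction, and 22 adjusted over the list alone. Quantile normalization called 54 of 169 of its windows higher, division by the median absolute deviation 102 of 156 and the test against the median 9 of 47. The neural list had 170 called, 85 in each direction, and 195 adjusted over the list alone, with 253 of 592, 394 of 579 and 44 of 183 higher in the same settings. The epithelial list had 35, with 15 higher and 20 lower, and 49 adjusted over the list alone. Muscle microRNAs had 18, with 7 higher and 11 lower, and 5 adjusted over the list alone. Broadly expressed microRNAs had 119, with 93 higher and 26 lower, and 111 adjusted over the list alone. The mir-34 family had 5, all higher, and 4 adjusted over the list alone. With quantile normalization 88 of 157 epithelial, 191 of 383 broadly expressed and 9 of 26 mir-34 called windows were higher, and after division by the median absolute deviation 68 of 99 muscle windows were. Over all regions 9.54% of windows were called.

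Taken line by line, MALME differed from MCF7 in 443 windows, 252 higher and 191 lower, and UACC62 in 30, 21 higher and 9 lower (limma, adjusted p under 0.05). At an unadjusted p under 0.05 the counts were 5252 and 7439. Fitted without UACC62, or without either of its arrays, MALME differed in 7415 windows, and fitted without MALME, UACC62 differed in 0. Without either MCF7 array or either MALME array both counts were 0. Without UACC62 replicate 1 or 2 the UACC62 count was 10512 or 3486. Quantile normalization called 3248 higher and 3554 lower in MALME, and 2009 higher and 2135 lower in UACC62. Dividing each array by its median absolute deviation called 4937 higher and 1922 lower in MALME, and 3180 higher and 732 lower in UACC62. Tested against the median difference, 172 were higher and 475 lower in MALME, and 29 higher and 61 lower in UACC62. The larger direction thus changed with the scaling and centring.

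The second comparison set the melanoma lines against each other. No window passed in UACC62 against MALME (limma, 0 of 20765), and 673 had an unadjusted p under 0.05, where 1038 would be expected with no difference. The windows with the smallest p, none of which passed, were higher in UACC62 by 0.75 (SE 0.19) in MIR370, 0.78 (SE 0.20) in MIR342, 0.77 (SE 0.20) in MIRLET7G and 1.05 (SE 0.19) in an unnamed region of chromosome 14, and by 0.79 in one of chromosome 7. The difference was -0.82 (SE 0.23) in MIR193B/MIR365A and -0.75 to -0.80 in 3 unnamed regions of chromosomes 4 and 11. In MIR31 it was -0.78 (SE 0.19), and its sign turned after loess within each array, to 0.13. Of 295 regions 0 passed, and 5 had an unadjusted p under 0.05. Power was higher for regions than for windows in the simulation, where 30 of 295 regions were changed. Of 8 regions changed by 0.5 on the log2 scale 62.5% were recovered, and of 8 changed by 1 87.5%. Between these 2 lines, too, the window differences correlated with Cy3 brightness across windows (r = -0.72). MALME 1 and 2 and UACC62 1 were scanned on one day and UACC62 2 on another. With scan day as a block, which equals the comparison within the shared day, 2 windows and 42 regions passed. Without UACC62 replicate 1, 10272 windows and 226 regions passed. Quantile normalization called 47 windows and 91 regions, and dividing by the median absolute deviation 0 windows and 39 regions.

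The replicates of a line did not resemble each other more than arrays of the other melanoma line. The mean correlation of the log2 ratio across probes was 0.818 within and 0.814 between MALME and UACC62, a difference under the standard deviation over pairs of 0.0508, and the closest pair was MALME replicate 2 with UACC62 replicate 1 (0.886). In the denoised ratios MCF7 stood apart, with 0.863 between its arrays and 0.569 to 0.781 with the melanoma arrays.

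Segments of low log2 ratio, called depleted here, were compared next. MALME had 1481 segments and UACC62 1495, of median length 120 bp, and 916 of those in MALME (61.9%) overlapped one in UACC62, against a mean of 149 when segments were shifted within regions. With Cy5 regressed on Cy3, MALME had 1058 segments and UACC62 483. Of those in MALME 219 (20.7%) overlapped one in UACC62, against 25.1 after shifting. UACC62 had far fewer segments to overlap in this setting, so 20.7% and 61.9% are not on the same scale. Single arrays of one line shared 64.5% (MALME) and 67.3% (UACC62) of segments, and arrays of different melanoma lines 56.7% to 72.2%. In the denoised ratios 354 of 1172 MCF7 segments (30.2%) overlapped a segment of both melanoma lines, against 63.7 after shifting. Shifting breaks the tie of segments to probe brightness, which low ratios followed, so brightness alone could give sharing above the shifts. The MCF7 comparison was not repeated with brightness taken out. With depletion set at the 5th percentile the shared counts were 325 and 107, and with segments of at least 50 bp they were 3376 and 2609. In the first 2 kb from the microRNA, the share of segments was 0.816 times the share of probes in MALME and 1.06 times in UACC62, within the range of shifted segments. In UACC62 it rose above that range with depletion at the 5th percentile (1.29, range 0.710 to 1.16) and with segments of at least 50 bp (1.14, range 0.869 to 1.09), where MALME stayed within it (0.991 and 1.02). From 14 to 16 kb the ratio of UACC62 was 0.729, under its range from 0.764, and 0.837 with segments of at least 50 bp, under 0.840. It was within its range at the 5th percentile (0.640, range from 0.609) and in the denoised ratios (0.913). At the 5th percentile the bin from 16000 to 18000 bp lay under its range in UACC62 (0.558, range from 0.643). In the denoised ratios, the first 2 kb stood at 0.783 in MALME and 1.00 in UACC62, both within their ranges. In MCF7, on the same values, it was 1.32 in the first 2 kb, above the shifted range of 0.819 to 1.22, and 0.549 from 14 to 16 kb, under the range from 0.737. In MCF7 these are 2 of 10 bins, and the difference between lines was not tested.

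Nucleosome spacing was not visible in the ratio. Its autocorrelation fell from 0.479 to 0.505 at 50 bp to between 0.310 and 0.321 at 400 bp, and no maximum after 100 bp rose by more than 0.0002. When Cy5 was instead regressed on Cy3 within each array, a choice made after seeing the data, the first maximum lay at 170 bp in MALME replicate 1 and at 180 bp in MALME replicate 2 and UACC62 replicate 1, with rises of 0.0095, 0.0151 and 0.0152. UACC62 replicate 2 rose by 0.0000 at its first maximum, and by up to 0.0052 at lags up to 300 bp.

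**Figure D3:**
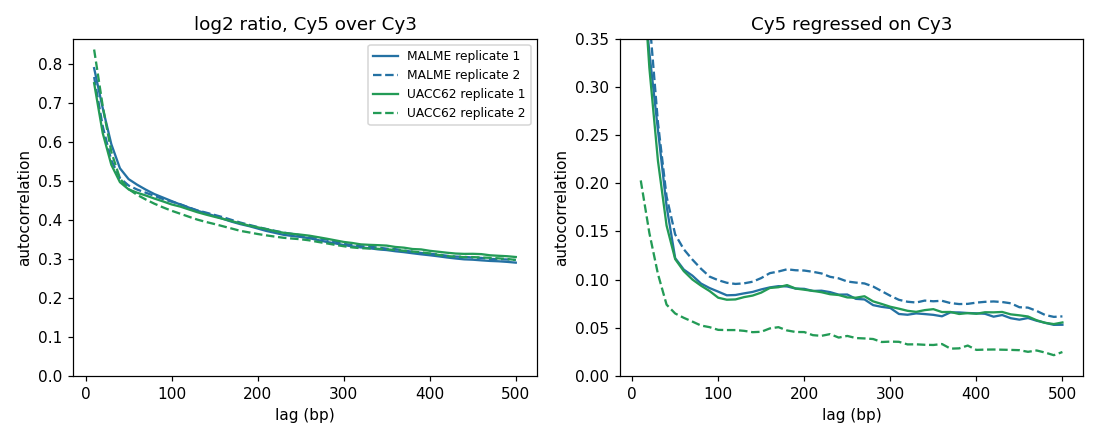
Autocorrelation along the tiling against lag (bp) for the 4 arrays of MALME and UACC62, for the log2 ratio (left) and for Cy5 regressed on Cy3 (right). The left curves rise by no more than 0.0002 after 100 bp, and 3 of the right curves, whose first lags lie above the panel, have a first maximum at 170 to 180 bp.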

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

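Several alternatives were chosen after the data were seen: Cy5 regressed on Cy3, single channels, crossed pairing, linear ratios, the floor of 0.01, the brightness regression, the test against the median difference and the denoised ratios for segment distance. The cause of each change below was not tested unless the setting itself changes what is tested.

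Dividing each array by its median absolute deviation gave 7495 windows for melanoma against MCF7, 6859 for MALME against MCF7 and 3912 for UACC62 against MCF7, with 155 regions for melanoma against MCF7 and 39 for UACC62 against MALME. Quantile normalization gave 7128, 6802 and 4144 windows and 167 regions in the same comparisons, and 47 windows and 91 regions for UACC62 against MALME. A trended robust prior gave 5602, 3567 and 5647 windows and 88 regions against MCF7, and 73 windows and 5 regions for UACC62 against MALME. Windows of 100 bp gave 3502, 1311 and 652 calls, windows of 400 bp 899, 13 and 2. The median of a window's probes gave 719 for MALME and 282 for UACC62 against MCF7. With only 2 lines in the fit these were 7415 and 0. With the melanoma arrays as 1 group of 4, 8 regions passed.

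Linear ratios gave 1 window for melanoma, 0 for MALME and 0 for UACC62 against MCF7, and 0 regions. A floor of 0.01 gave 1040, 155 and 0 windows and 8 regions. Regression on genomic channel brightness gave 4965, 4996 and 2582 windows and 121 regions. Tested against the median difference, 90 windows passed for UACC62 against MCF7 and 4 regions for melanoma against MCF7. For UACC62 against MALME, Cy3 alone gave 57 windows and 120 regions, and Cy5 regressed on Cy3 and scaled by the median absolute deviation gave 28 regions.

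Leaving out each array in turn gave 0 to 10272 windows and 0 to 226 regions for UACC62 against MALME, 0 to 10126 windows and 0 to 167 regions for melanoma against MCF7, 0 to 7415 windows for MALME against MCF7 and 0 to 10512 for UACC62 against MCF7. The array left alone in its line was assumed to vary like the other lines. The highest counts came without UACC62 replicate 1, for MALME against MCF7 without either UACC62 array.

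The replicate numbers are only shared numbers: deviations of same-numbered arrays correlated at -0.13 for MALME and UACC62 in the scanner values and at -0.01, -0.01 and -0.15 in the denoised ratios. With the replicate number as a block, 416 windows and 31 regions passed for melanoma against MCF7, 0 windows for MALME and 0 for UACC62 against MCF7, and 0 windows and 0 regions for UACC62 against MALME. Crossed pairing gave 0 windows and 2 regions for UACC62 against MALME.

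Of the 20 named windows between melanoma and MCF7, 17 passed with the block, 17 with the trended prior, 17 with the floor of 0.01 and 0 with linear ratios. Among the 10 named between UACC62 and MALME, the window of MIR31 turned to 0.13 after loess, to 0.15 with Cy5 regressed on Cy3 and to 0.15 with that regression scaled.

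Segments shared by MALME and UACC62 numbered 325 at the 5th percentile, 3376 at a minimum of 50 bp, 219 with Cy5 regressed on Cy3 and 985 to 1141 with an array left out. Those shared with MCF7 numbered 107, 2609 and, with an array left out, 368 to 451. The mean ratio in the first 2 kb rose from 0.940 to 1.14 at the 5th percentile, with UACC62 at 1.29, above its shifted range, and MALME at 0.991, within it. The mean rise of the autocorrelation was 0.0002 in the denoised ratios, 0.0014 in Cy5 alone and 0.01 with Cy5 regressed on Cy3. Random-sequence probes at 64.1% or more of the median Cy5 intensity limit how deep a depletion can be read.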

Other observations

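Regions not described above, chosen after their values were seen, also held many windows called between the melanoma lines and MCF7. MIR599 inside VPS13B had 19 higher and 1 lower in melanoma, and MIR551B had 18 higher and 2 lower. In MIR132/MIR212 and in MIR214/MIR199A2 inside DNM3 all 15 called windows were higher. MIR129-1 had 4 higher and 15 lower, MIR33A inside SREBF2 had 3 higher and 9 lower, and MIR223, a microRNA of myeloid cells, had 4 higher and 9 lower. The mean of none of these regions passed (limma, adjusted p from 0.0503 for MIR599 and MIR551B to 0.949 for MIR223).

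The tests of separate nucleosomes, of the Cy5 floor, of a missing mononucleosomal pattern and of the spread of UACC62 replicate 2 were chosen after the result was seen, as was a control in the copy number test.

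Whole regions, MIR21 first, were shifted between the melanoma lines and MCF7. After a regression on probe brightness 18 of the 19 regions stayed called, with MIR21 at 0.91 before and 0.69 after. The regression also lowered the median SE from 0.085 to 0.035 and called 121 regions, so a smaller shift could stay called. That brightness was the mean Cy3 of the MALME and UACC62 arrays, so a response to the Cy3 of MCF7 was not removed. Brightness so measured did not remove the calls, but a part played by brightness stays open. Shifts of adjoining regions under 10 Mb apart correlated at 0.297 over 194 pairs, above the 95th percentile of shuffled regions of 0.121. After the brightness regression they correlated at 0.435, above 0.120 in shuffled regions. A shift shared along a chromosome, as copy number gives, may account for this. Between MALME and UACC62 the genomic channel difference of one pair of arrays correlated with the ratio difference of the other pair at -0.821, but arrays of the same line gave -0.820, a control added after -0.821 had met its prediction, so copy number and an array-wide response to brightness cannot be told apart there. Changes at separate nucleosomes stay open, since a median of 80.8% of the windows of the 19 regions lay above the median window difference, from 66.7% to 97.7% (median 90.9% above zero), and these regions were picked for their shift, as do, untested, a difference in chromatin and a batch shared by the MCF7 arrays.

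The log2 ratio fell as the genomic channel rose. Part of this is built in, since Cy3 is the denominator of the ratio. The standard deviation of log2 Cy3 was 1.28 to 1.64 over the 4 arrays, against 0.46 to 0.96 for log2 Cy5. Random-sequence probes reached at least 64.1% of the median Cy5 intensity on every array and at most 49.9% of the median Cy3 intensity, so a high floor of Cy5 may flatten that channel and leave Cy3 to set the ratio. A Cy5 channel without mononucleosomal pattern was tested by the autocorrelation of Cy5 regressed on Cy3. On MALME 1, MALME 2 and UACC62 1 it rose at its first maximum by 0.0095 to 0.0152 (standard error over resampled regions up to 0.0035). Cy3 alone rose by at most 0.0006. The comparison is unlike, since Cy3 was not regressed on anything, and Cy5 alone rose by 0.0025, 0.0009 and 0.0010 on these arrays. A pattern left by the regression on Cy3 is thus not excluded. On UACC62 2 a missing pattern stays open too, with 0.0000 at the first maximum and 0.0052 (standard error 0.0024) as the highest rise up to 300 bp. No biological explanation was tested.

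No window was called between UACC62 and MALME. Dividing each array by its median absolute deviation still gave 0 windows, but 39 regions, a lowest adjusted p of 0.0726 in place of 0.664 and 2576 in place of 673 windows with an unadjusted p under 0.05, and quantile normalization called 47 windows. The wide spread of UACC62 replicate 2 therefore stays open. Low power may account for it, since 0% of simulated windows changed by 1 on the log2 scale were recovered. The simulated spreads included that of UACC62 replicate 2, so the simulation cannot tell the number of arrays, 2 per line, from that wide spread. Similar nucleosome positions in both lines stay open.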
